A study of Caenorhabditis elegans with 4 samples.

How the data were processed

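The data come from chromatin immunoprecipitation followed by sequencing (ChIP-seq) of EGL-27 in whole Caenorhabditis elegans at the third larval stage (L3). Per the labels, the worms were pooled males and females of strain OP177, which stably expresses EGL-27 with a C-terminal GFP-FLAG tag from the transgene wgIs177, and chromatin was sheared by sonication. EGL-27 is an MTA-family protein with a GATA-type zinc finger, the family that forms part of the NuRD chromatin remodelling complex. The 4 samples form 1 group and are numbered as biological replicates 1 to 4 in the labels. No second group was compared, so every comparison sets peaks of one kind against other peaks, or replicates against each other.

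Per the deposited README texts, the authors called peaks and background on each replicate's alignment against a control alignment shared by all replicates. By the same texts, the pooled list was called on the 4 replicate alignments together with that control. The final list was derived from the pooled and replicate lists by the irreproducible discovery rate (IDR), a measure of how alike peaks rank between replicates. The aligner, peak caller, filters and IDR threshold are not given in the sources used here. Each list was deposited on the builds ce10 and ce11, and 12 peak lists were used. The deposited score of each peak is the authors' signal value, whose scale is not given in the sources used here, so it was used here only to rank peaks within a list. The deposited −log10 q-value took a single value, 2.22, for all 814 peaks of the ce11 IDR list and was not used to rank peaks. The number of reads per library is not in the files used here, so the sequencing depth behind each peak is unknown. Depth differences between libraries and the shared control can change how many peaks a list holds.

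All main results use ce11, which is the assembly WBcel235. No peak end lay beyond the end of its chromosome in the reference. Gene models came from Ensembl release 115, with names of mitochondrial genes from RefSeq matched by position. The ce10 lists served only as an alternative for peak counts, the share of peaks on the X chromosome and the agreement between replicates, and no coordinates were converted between builds. Analyses ran in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.

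Because the lists differ in length, replicates were compared at the same number of peaks, the 814 with the highest score, which is the length of the IDR list. Peaks counted as shared when their summits lay within 200 bp. The level given by chance and a one-sided permutation p came from 1000 circular shifts of one list along each chromosome, for which 0.001 is the smallest p possible. A promoter window ran from 1000 bp upstream to 200 bp downstream of the annotated 5′ end of a protein-coding gene. Shares of IDR peaks were compared with those of the 27242 other peaks of the pooled list by Fisher's exact test, two-sided, with the conditional odds ratio and its 95% interval. Peaks are not replicates of the experiment: these p-values describe the lists, and the spread between replicates is given as mean ± SD over the 4 replicates. Replicates share 1 control, so part of their overlap may come from it.

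Gene lists, 22 in number, and 18 sequence motifs were fixed before the data were examined, as were the main tests. A gene counted as bound when an IDR summit lay in its promoter window, and the background was the 7496 protein-coding genes with any pooled summit there. Motifs were searched on both strands within 50 bp of the summit, and compared with 814 other pooled peaks matched on promoter class and on GC content in 10 strata. Non-coding genes were those within 200 bp of a summit, in 10 annotation classes. Benjamini-Hochberg adjustment ran over the lists, the motifs or the classes. Of the list members named beforehand, 9 symbols had no annotated gene of that name; the microRNAs of the heterochronic list were among them.

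The methods were tested on simulated data. For replicate agreement, a planted overlap of 30% of 800 peaks was recovered as 30.1%, and 0 of 28 unrelated pairs reached a permutation p of 0.05. For gene lists, 2 of 200 random lists of 70 genes reached p = 0.05 in Fisher's exact test, and 50 of 50 lists of 70 genes with 20 bound members were called. For motifs, 1 of 90 tests on unselected peaks reached p = 0.05 in the same exact test, and a motif planted in 120 of 814 windows was the 1 motif called among 18. The unselected peaks were 1 set, tested against repeated draws from the other weaker pooled peaks. The motif simulation therefore did not hold the difference in coding exons between IDR peaks and the other peaks.

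The genes named in the text follow a rule fixed beforehand: egl-27, the genes at the 15 strongest IDR peaks, and up to 4 members with the strongest IDR peaks of each list that passed an adjusted p of 0.05 and of 8 lists tied to EGL-27 (Hox and Wnt, NuRD and synMuv, GATA factors, heat shock, oxidative stress, insulin and TOR, heterochronic, seam and epidermis). GATA and Hox genes without a peak could be named too. Because 9 of the 15 strongest peaks were mitochondrial, the 15 strongest nuclear peaks were added after the values were seen, as were the genes at non-coding loci. Alternatives covered the number of top peaks, the shared distance, each replicate left out in turn, the promoter window, the background, the stronger 407 IDR peaks, the region around egl-27 and the genome build. The IDR list cannot be remade without a replicate from these files, so results that rest on it were not recomputed that way.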

Results

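EGL-27 occupancy in L3 larvae was measured by ChIP-seq in 4 biological replicates of 1 strain, and the data are the authors' lists of peaks. The IDR list held 814 peaks, 802 of them on nuclear chromosomes. The pooled list held 28056 peaks, and the IDR peaks were the 814 with the highest score in it. Membership of the IDR list thus equals a cutoff on the pooled score, not agreement of the replicates peak by peak. Replicates 1 to 4 had lists of 30000, 6602, 19304 and 12990 peaks, a mean of 17224 ± 9972 (SD, n = 4). The replicate and pooled lists hold peaks and background, so their lengths and the mean are not numbers of sites found. The lowest −log10 q-value was 0.0177 in the pooled list and 0.0955 in that of replicate 1. Whether the list of replicate 1, with its round length, was limited to a set number of peaks is not given in the sources used here. The read depth of the libraries is unknown.

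The first question was how far the replicates located the same sites. Among the 814 strongest peaks of each replicate, replicates 1 and 4 shared 36.0% and replicates 1 and 3 shared 35.9%. Replicates 3 and 4 shared 27.6%. The 3 pairs with replicate 2 shared less: 20.6% with replicate 3, 20.5% with replicate 1 and 17.2% with replicate 4. Shifted lists gave a mean of 0.326% to 2.35% per pair, and 3.38% at most. No shift reached the observed share in any of the 6 pairs (permutation p = 0.001 for each, the smallest possible). The highest mean, 2.35%, was that of replicates 2 and 3, the 2 lists with mitochondrial peaks. Part of the overlap may come from the control shared by the replicates.

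Of the 814 IDR peaks, 67.2% lay at a top peak of replicate 1, 49.6% of replicate 3, 48.2% of replicate 4 and 29.2% of replicate 2, a mean of 48.6% ± 15.5 (SD, n = 4). With the full lists these shares were 97.8%, 91.4%, 85.4% and 55%. The IDR peaks are the strongest of the pooled alignments, so each share sets a replicate against a pool that contains it. It also follows how much each library adds to the pooled signal, and read depth is unknown. A top peak was present in all 4 replicates at 67 IDR peaks, in 3 at 161, in 2 at 297, in 1 at 236 and in none at 53. The 67 peaks had a median rank of 64 in the IDR list, and the 53 peaks a median rank of 695. Because the ranks come from the pooled replicates, part of this link is built in. The count of 67 depended on replicates 2 and 4: it was 156 without replicate 2 and 103 without replicate 4.

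**Figure D1:**
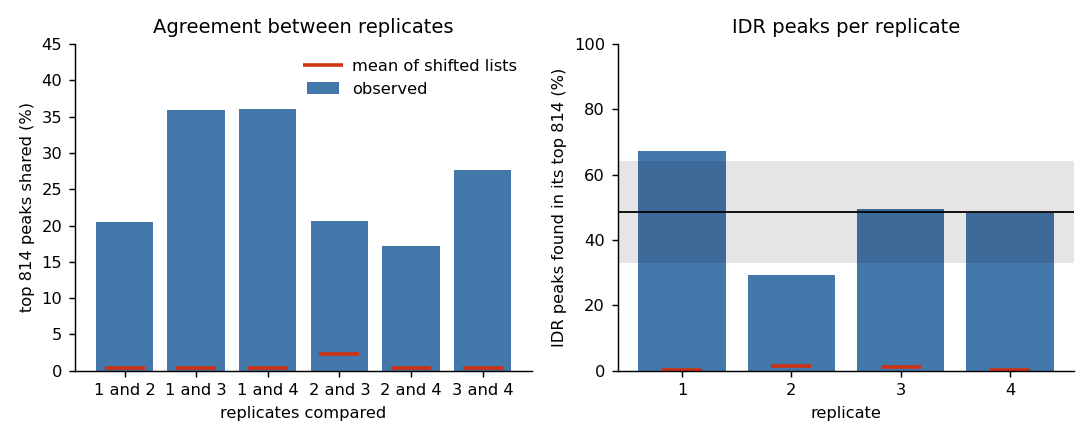
Left, share of the 814 strongest peaks (%) that each pair of replicates had in common, with the mean of 1000 shifted lists as a red line; right, share of the 814 IDR peaks (%) found among the 814 strongest peaks of each replicate, with the mean (line) and SD (band) over the 4 replicates and the mean of shifted lists in red. Observed shares of pairs run from 17.2% to 36.0%, and replicate 2 holds 29.2% of the IDR peaks against 48.2% to 67.2% in the other replicates.

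The second question was where in the genome the peaks lay. Promoter windows of protein-coding genes held 48.9% of the IDR summits (398 of 814), against 26.7% of the other pooled peaks (7265 of 27242). The odds ratio was 2.63 (95% interval 2.28 to 3.03, Fisher's exact p = 4.2e-40), and shifted lists gave 21.8% on average and 27% at most (permutation p = 0.001, the smallest possible). In the replicates, 42.1% ± 3.04 (SD, n = 4) of the top 814 summits and 26.9% ± 0.807 of the remaining summits lay in promoter windows. Coding exons outside these windows held 1.6% of IDR summits and 17.9% of the others (odds ratio 0.0744, exact adjusted p = 4.0e-49). Introns held 21.7% against 28.9% (exact adjusted p = 1.2e-05). Intergenic DNA held 26.3% against 23.2%, a difference that did not pass (exact adjusted p = 0.0521). The promoter share fell along the pooled ranking, from 48.9% to 44% in the next 814 peaks and 23.2% in the weakest 15032. Against those next 814 peaks alone the odds ratio was 1.22 and did not pass (Fisher's exact p = 0.0526), so the contrast is one with the weaker pooled peaks.

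**Figure D2:**
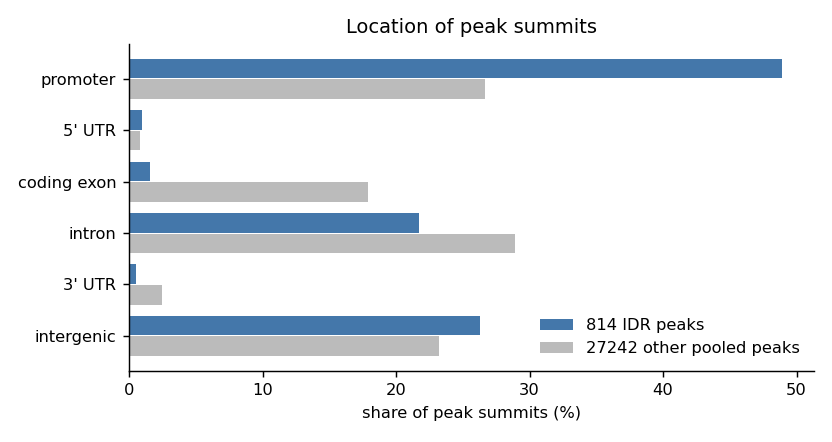
Share of peak summits (%) by annotation for the 814 IDR peaks (blue) and the 27242 other pooled peaks (grey), each summit counted once with promoter windows first. Promoter windows hold 48.9% of IDR summits against 26.7%, and coding exons 1.6% against 17.9%.

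Of the 398 IDR peaks in promoter windows, 111 (27.9%) lay in the windows of genes on both strands, so that they cannot be given to 1 gene. Among the other pooled promoter peaks the share was 13% (odds ratio 2.59, 95% interval 2.04 to 3.28, Fisher's exact p = 2.3e-14). In the replicates it was 22.3% ± 4.08 of top promoter peaks (SD, n = 4).

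The X chromosome carried 25.6% of the IDR peaks (208) and 19.2% of the other pooled peaks (odds ratio 1.45, 95% interval 1.23 to 1.70, Fisher's exact p = 1.2e-05, adjusted p = 4.2e-05 over 7 chromosomes). No autosome passed the adjusted threshold. Of the next 814 pooled peaks 21.3% were on X, and against these alone the odds ratio was 1.27 (Fisher's exact p = 0.0465, not adjusted). That is a smaller contrast than with all other pooled peaks. In the replicates the X share was 23.4% ± 2.51 (SD, n = 4) of top peaks and 19.4% ± 0.409 of the rest, and it was larger among top peaks in 4 of 4. The 95% interval of the odds ratio lay above 1 in replicates 1 (odds ratio 1.59) and 3 (1.25), and included 1 in replicates 2 (1.11) and 4 (1.18). Outside promoter windows 31.3% of IDR peaks and 20.2% of other peaks were on X (odds ratio 1.80, Fisher's exact p = 1.4e-07). Inside them the shares were 19.6% and 16% (odds ratio 1.24, 95% interval 0.946 to 1.6, Fisher's exact p = 0.111).

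Among the 15 strongest IDR peaks, 6 were nuclear and 9 mitochondrial. The strongest nuclear peak lay in an intron of egl-27 itself (WBGene00001194; chromosome II, peak 6842704 to 6842888, rank 5, ce11). It was followed by a peak 181 bp upstream of cdc-48.1 (II, 10563495 to 10563675), which encodes an AAA ATPase of protein quality control, and by a peak 275 bp upstream of rpl-3 (III, 3867507 to 3867675), a ribosomal protein gene. The other 3 lay in introns of Y111B2A.12 (III, 12612546 to 12612770) and pqn-41 (III, 1925252 to 1925439), and in intergenic DNA 6391 bp from the 5′ end of Y37A1A.2 (IV, 13919318 to 13919488). All 6 were among the top peaks of the 4 replicates.

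Among the 15 strongest nuclear peaks, a set chosen after the values were seen, were peaks at nspc-17, at the paired promoters of iff-2 and F54C9.14, tasp-1 and K01G5.10, and rpl-15 and K11H12.8, and intergenic peaks nearest to W02H3.3, ogt-1, F20B6.9, K02D3.1 and fbxb-58. The iff-2 gene encodes a translation initiation factor of the eIF-5A family, and its 5′ end lay 79 bp from the summit (II, 8561360 to 8561518). The 9 mitochondrial summits of the first 15 all lay in coding sequence, those of ranks 1 and 3 in ND5 and others in ND1, COX3 and COX1. The summit of rank 2, at 4733, lay in none of these genes but 945 bp upstream of COX3. Mitochondrial genes lie so close together that promoter windows there cover neighbouring genes, so these peaks are given by position only. Mitochondrial DNA held 12 of the 814 IDR peaks. The lists of replicates 2 and 3 had 29 and 23 mitochondrial peaks, all among their strongest 814, and those of replicates 1 and 4 had 0.

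The third question was which genes had an IDR peak in the promoter window. Of 7496 protein-coding genes with any pooled peak there, 519 (6.92%) had one. Genes of cytosolic ribosomal proteins, of chaperones and of the respiratory chain had IDR peaks more often than this, and they were the 3 of 22 lists past an adjusted p of 0.05 (Fisher's exact test). For ribosomal proteins, 26 of 70 genes had a peak (37.1%, odds ratio 8.30, 95% interval 4.86 to 13.9, exact adjusted p = 5.3e-12). The strongest were at rpl-3 (rank 9), rpl-15 (rank 24), rpl-35 (rank 28) and rpl-20 (rank 42), with summits 275, 359, 438 and 290 bp upstream of the 5′ end. The rpl-20 summit was nearer to the 5′ end of Y17G9B.5. Ribosomal protein genes with a top peak numbered 23, 14, 16 and 13 in replicates 1 to 4.

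Of 17 heat shock and chaperone genes, 7 had an IDR peak (41.2%, odds ratio 9.52, 95% interval 3.06 to 27.8, exact adjusted p = 0.00085). The strongest were at dnj-13 (rank 70), hsp-1 (rank 296), hsp-110 (rank 358) and hsp-60 (rank 362). These encode a DnaJ co-chaperone, a cytosolic Hsp70, an Hsp110 and the mitochondrial Hsp60, and the other 3 were hsp-3, dnj-19 and dnj-12. The peaks at hsp-110, hsp-60 and dnj-19 lay nearer to the 5′ ends of rpn-3, Y22D7AL.10 and nhr-47, and with each summit given only to the nearest 5′ end the list had an odds ratio of 7.93 (exact adjusted p = 0.0310). In the replicates 4.00 ± 0.816 (SD, n = 4) of these genes had a top peak.

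Of 29 respiratory chain genes, 7 had an IDR peak (24.1%, odds ratio 4.32, 95% interval 1.55 to 10.5, exact adjusted p = 0.0219). The strongest were cox-5A (rank 51) and cox-5B (rank 263) of cytochrome c oxidase, sdha-1 (rank 195) of succinate dehydrogenase and atp-1 (rank 244) of the ATP synthase, all nuclear genes. The summit 229 bp upstream of sdha-1 also lay within 200 bp of the snoRNA gene D2021.6, so that peak cannot be given to sdha-1 alone. In the replicates 4.25 ± 1.26 (SD, n = 4) of the respiratory chain genes had a top peak. With the stronger 407 IDR peaks this list no longer passed (odds ratio 4.51, exact adjusted p = 0.0933).

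**Figure D3:**
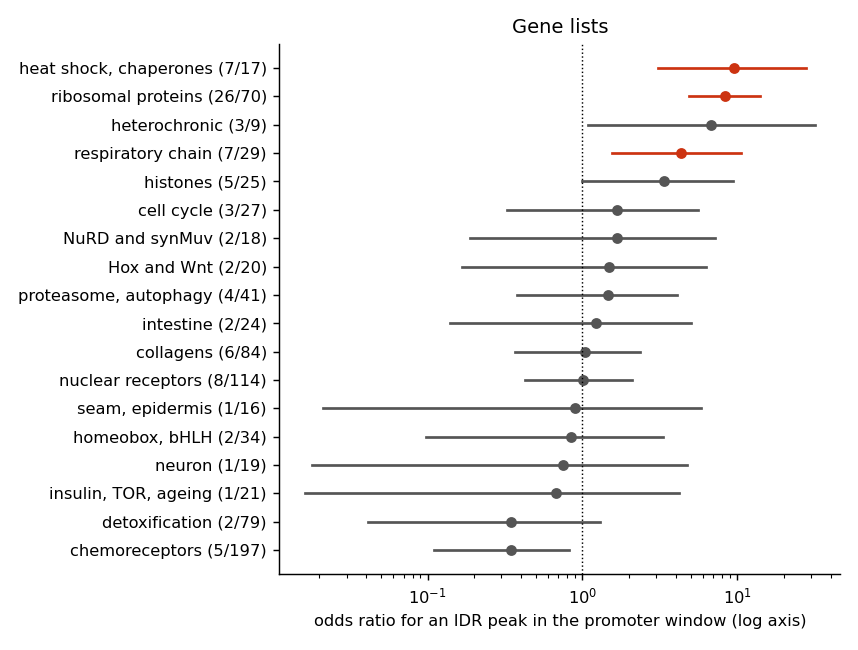
Odds ratio (log axis) with 95% interval for an IDR peak in the promoter window, for the 18 of 22 gene lists with at least 1 such gene; the numbers give genes with an IDR peak and genes with any pooled peak, and red marks an adjusted p at or under 0.05. Heat shock (9.52), ribosomal proteins (8.30) and respiratory chain (4.32) are the lists in red.

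EGL-27 is known for roles in Wnt signalling, cell polarity and larval patterning, so lists of these genes were set beforehand. Of 20 Hox and Wnt genes 2 had an IDR peak, mig-5 (rank 574) and dsh-2 (rank 725), both coding for Dishevelled proteins, the first in a promoter region shared with cct-1 (odds ratio 1.5, exact adjusted p = 1). The dsh-2 peak was a top peak in none of the replicates. The Hox genes ceh-13, egl-5 and nob-1 had only weaker pooled peaks in the window, from a list that also holds background. The genes lin-39, mab-5 and php-3 had none. Of 18 NuRD and synMuv genes 2 had an IDR peak, lin-54 (rank 91) of the DREAM complex and lin-53 (rank 268), a histone-binding protein (odds ratio 1.68, exact adjusted p = 0.946). Neither peak can be given to these genes alone: the first lay 22 bp from the 5′ end of rpl-12 and 371 bp from that of lin-54, and the second 211 bp from that of nra-2 and 256 bp from that of lin-53. Of 9 heterochronic genes, which time larval development, 3 had an IDR peak. They were nhl-2 (rank 33, a top peak in 4 replicates, shared with tag-340, whose 5′ end is nearer), lin-66 (rank 312) and lin-14 (rank 771), and the list did not pass (odds ratio 6.75, 95% interval 1.09 to 31.7, exact adjusted p = 0.0890; with the nearest 5′ end only, 6.32 and 0.337).

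Of 5 GATA factor genes with a pooled peak 0 had an IDR peak in the window (upper bound of the odds ratio 14.7, exact adjusted p = 1). The strongest pooled peaks were those of elt-2 (rank 1516) and egl-27 (rank 1731). Of 11 oxidative stress genes 0 had an IDR peak (upper bound 5.36, exact adjusted p = 1). Of 21 insulin, TOR and ageing genes 1 had a peak, rheb-1 (rank 311, nearer to spk-1, odds ratio 0.672, exact adjusted p = 1), and of 16 seam and epidermal genes 1, spc-1 (odds ratio 0.896, adjusted p = 1), which encode a Rheb GTPase and alpha spectrin. With lists this short the intervals leave room for sizeable differences in either direction.

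The remaining lists did not pass. Histones had 5 of 25 genes with an IDR peak (exact adjusted p = 0.0957). Chemoreceptors had 5 of 197 (2.54%, odds ratio 0.344, exact adjusted p = 0.0543). Collagens had 6 of 84, nuclear receptors 8 of 114, the proteasome and autophagy 4 of 41, cell cycle 3 of 27, homeobox and bHLH factors 2 of 34, detoxification 2 of 79, intestine 2 of 24, neurons 1 of 19, muscle 0 of 20 and the germline 0 of 16, with adjusted p from 0.553 to 1.

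Non-coding genes were a further place of strong peaks. They were tested because RNA polymerase III and small RNA loci are frequent ChIP targets or artefacts. The samples hold no ChIP of another protein. Peaks particular to EGL-27 therefore cannot be told here from loci that give peaks in many ChIP experiments. The same holds for the gene lists above. Within 200 bp of a tRNA gene lay 8.11% of the IDR summits (66) and 1.28% of the others (odds ratio 6.78, adjusted p = 5.9e-29, Fisher's exact test). For snoRNA genes, whose products guide RNA modification, the shares were 4.55% (37) and 0.389% (odds ratio 12, exact adjusted p = 2.6e-24). For snRNA genes they were 1.23% (10) and 0.162% (odds ratio 7.69, exact adjusted p = 7.5e-06). Other ncRNA genes were near 21% against 6.97% (odds ratio 3.55, exact adjusted p = 9.5e-36), antisense RNA genes near 0.614% against 0.136% (odds ratio 4.54, adjusted p = 0.0118), and pseudogenes near 0.491% against 1.80% (odds ratio 0.270, adjusted p = 0.0051). MicroRNA, lincRNA, piRNA and rRNA genes did not pass. The antisense call ended with the stronger 407 IDR peaks (odds ratio 3.63, exact adjusted p = 0.160), and the pseudogene call ended outside promoter windows (odds ratio 0.334, exact adjusted p = 0.0899). In the replicates 6.02% ± 0.783 (SD, n = 4) of top summits and 1.25% ± 0.233 of the rest lay at tRNA genes, and 3.22% ± 0.811 and 0.522% ± 0.109 at snoRNA genes.

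Outside protein-coding promoter windows, a comparison added after the data were seen, tRNA genes were near 11.5% of 416 IDR peaks and 1.42% of the others (odds ratio 9.07, exact adjusted p = 5.6e-26). Many of the IDR peaks at tRNA genes lay on X. The excess at tRNA genes and the X excess outside promoter windows thus overlap, and no test separated them. Among the snRNA class were genes of the SL2 spliced leader RNA, which is joined to downstream messages of operons. Singled out after their values were seen, 6 of 18 SL2 genes had an IDR peak within 200 bp, the strongest at sls-2.4 (I, 4172000 to 4172369, rank 41) and sls-2.1 (II, 5844788 to 5845157, rank 57).

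**Figure D4:**
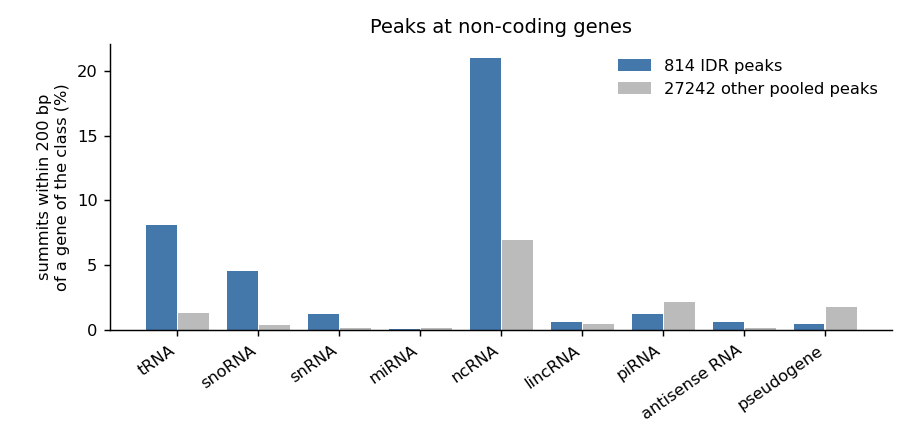
Share of summits (%) within 200 bp of an annotated non-coding gene or pseudogene, by class, for the 814 IDR peaks (blue) and the 27242 other pooled peaks (grey); rRNA genes, with 0 peaks, are not drawn. Peaks at tRNA genes make up 8.11% of the IDR list against 1.28%, and peaks at snoRNA genes 4.55% against 0.389%.

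Of the 18 motifs, the GAGA repeat GAGAGAG was the 1 past an adjusted p of 0.05 against the matched background. It occurred within 50 bp of 13.6% of IDR summits (111) and 6.39% of matched summits (52; odds ratio 2.31, 95% interval 1.62 to 3.33, Fisher's exact adjusted p = 2.4e-05). In the replicates, without matching on promoter class or GC content, it was near 11.1% ± 3.86 (SD, n = 4) of top summits and 3.02% ± 0.129 of the rest. These shares are therefore not a repeat of the matched comparison. Against all other pooled peaks, also unmatched, the GAGA odds ratio was 4.22. The call ended when peaks in coding exons were left out of both sets, an alternative added after the data were seen (odds ratio 1.39, exact adjusted p = 0.138). The GATA motif WGATAR, the site type of proteins with such zinc fingers, was near 20.1% and 16.8% (odds ratio 1.25, 95% interval 0.963 to 1.62, exact adjusted p = 0.312). In the replicates, again without matching, it was near 22.6% ± 1.61 of top summits and 21.2% ± 0.413 of the rest. Its direction turned against flanking windows (odds ratio 0.898) and against unmatched peaks (odds ratio 0.921). The E-box CACGTG was near 6.02% and 3.44% (odds ratio 1.80, exact adjusted p = 0.171), but whether it passed varied between settings and between draws of the background. It passed in 11 of 20 other matched draws, within 100 bp of the summit (odds ratio 1.77, exact adjusted p = 0.0218), against flanking windows (3.41), against unmatched peaks (2.60), without mitochondrial peaks (2.2, adjusted p = 0.0212) and without peaks in coding exons (2.68, adjusted p = 0.0048). It did not pass within 25 bp, with the stronger 407 IDR peaks or without the egl-27 region (odds ratios 1.24, 2.15 and 1.83). Each setting with a matched background also drew a new background, so these E-box calls cannot be put down to the setting alone.

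The strain carries an egl-27 transgene, so the region of egl-27 (II, 6835008 to 6847908) was examined on its own. Within 20 kb of the gene lay 10 IDR peaks, 5 of them inside it, with ranks from 5 to 565. The strongest had its summit at 6842795, in an intron between exons that end at 6842605 and start at 6845360. It ranked 1 in replicates 1 and 4, 24 in replicate 2 and 17 in replicate 3. These ranks count mitochondrial peaks, which held rank 1 in replicates 2 and 3 and were absent from the other lists of single replicates. The top peaks of replicates 1 to 4 numbered 11, 12, 16 and 19 in this region. The pooled list had 59 peaks there, against a median of 11 around all 19973 nuclear protein-coding genes. Leaving the region out changed no call of the promoter, X chromosome or gene list comparisons, while the count of motifs past the threshold became 3. That setting also drew a new matched background, and other draws alone gave 1 to 6 motifs. The change in the count therefore cannot be put down to the region.

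**Figure D5:**
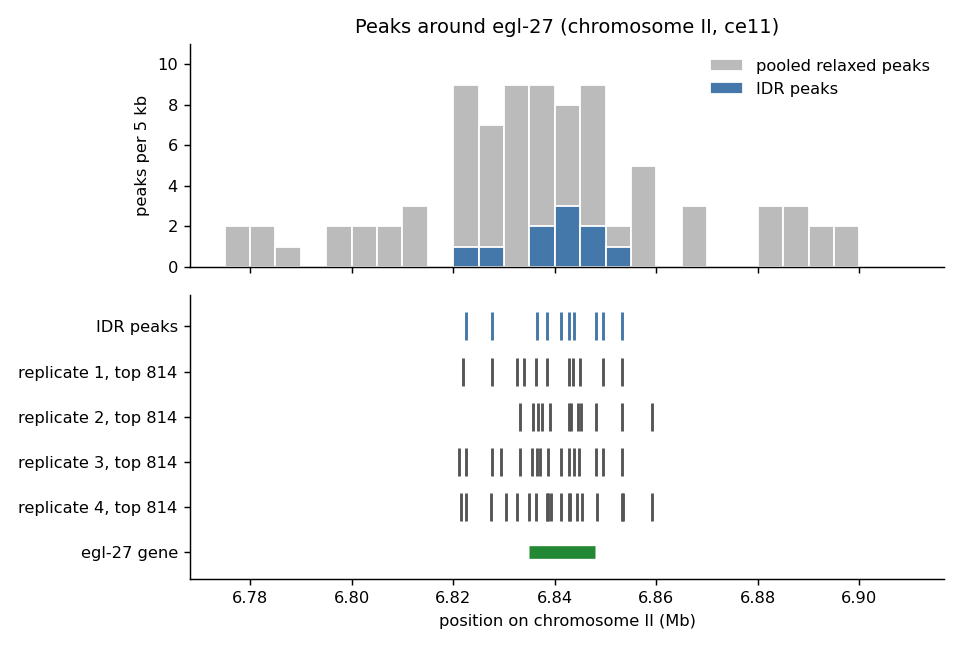
Peaks around egl-27 on chromosome II (ce11, position in Mb): above, pooled peaks (grey) and IDR peaks (blue) per 5 kb; below, summits of IDR peaks and of the 814 strongest peaks of each replicate within 20 kb of the gene (ticks), with egl-27 in green. Pooled peaks number 7 to 9 in every 5 kb bin from 6820008 to 6850007 and 0 to 3 in the bins before 6820008.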

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

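Of 23 values compared across the 4 replicates, 1 stood apart from the others. Among the peaks below the 814 strongest, the share at tRNA genes was 1.59% in replicate 4, and from 1.11% to 1.17% in the other replicates. Its gap to the nearest replicate was 0.861 of the whole range, above Dixon's 95% critical value for 4 samples. Chance puts about 1 in 20 such sets past it. No explanation was tested for it.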

How the results depend on the processing

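Of 72 alternative settings for the main results, 58 kept the direction and the side of the threshold of a test, moved a value without a test by less than 1 SD, or left a count within 1.5 times the reported one. All settings run for replicate agreement (20.9% to 33.2%), the IDR peaks per replicate (38.5% to 82.4%), the X share (odds ratio 1.27 to 1.47), and divergent promoters (2.55 to 2.67) were among them. Counts that changed within that factor were the non-coding classes (5 instead of 6 with the stronger 407 peaks and outside promoters), the IDR peaks (712 on ce10 instead of 814), the gene lists (2 with the stronger 407 peaks and 4 with 2000 bp upstream, instead of 3) and the IDR peaks with a peak in every replicate (78 without replicate 1 and 92 without replicate 3, instead of 67). Settings without mitochondrial peaks, on other lists of ce10 for agreement, with all transcripts, outside promoters, without coding exons and with other matched draws were chosen after seeing the data. The promoter odds ratio was 1.22 against the peaks ranked just below the IDR peaks, and 2.29 to 2.87 otherwise. The mean promoter share of the top 2000 peaks per replicate was 38.2%. IDR peaks with a peak in every replicate numbered 125 with the top 2000 peaks and 339 with full lists, as longer lists must give at least as many, and 78 to 156 with a replicate left out, as fewer lists must. Against all protein-coding genes 5 gene lists passed, the heterochronic genes and chemoreceptors added. With each summit given only to the nearest 5′ end, 14 of the 21 named list members had a peak. The number of motifs past the threshold was the least stable: 3 without the egl-27 region, 3 within 100 bp, 10 against flanking windows, 10 against unmatched peaks, 2 without mitochondrial peaks, 2 without coding exons and up to 6 in other matched draws. GAGA passed in 20 of 20 such draws (odds ratio 1.82 to 2.63), the E-box in 11 of 20 and GATA in 5 of 20 (1.1 to 1.63); GATA reversed to 0.898 against flanking windows and 0.921 against unmatched peaks. Where no construction is named, the cause was not tested. Motif settings with a matched background also drew a new background, so a changed count there cannot be put down to the setting alone. Unknown read depth limits any reading of a peak missing from the shorter list of replicate 2.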

Other observations

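The tests of the mitochondrial peaks, of X peaks outside promoters, of intervals per replicate, of the octamer and of gene families and hexamers were chosen only after the results they bear on were seen. Of the 32 X peaks among the 100 strongest IDR peaks, 9 carried the octamer GCGCAGGG, the core of a motif known from the sites that recruit the dosage compensation complex to X. This motif was searched once, within 100 bp of the summits. It was at 13 of 208 X peaks of the IDR list (6.25%) and at 12 of 5228 other pooled X peaks (0.230%; odds ratio 28.9, 95% interval 12 to 70.3, Fisher's exact p = 9.0e-13). It was at 1 of 594 autosomal IDR peaks. The share on X was larger among top peaks than in the rest of the list in 4 of 4 replicates (5.02% to 6.01% against 0.145% to 0.448%). Of 167 other orders of the same bases, 0 were at as many X IDR peaks, and the highest had 5. The 13 peaks had a median rank of 53, 11 lay outside promoter windows, and 11 were top peaks in at least 3 replicates. The strongest lay in intergenic DNA at summit 11094184 (rank 16), in the promoter window of nspc-17 at 14525864 (rank 18) and in intergenic DNA at 4209245 (rank 21), and another was 4839 bp from the 5′ end of xol-1, the switch gene of sex determination and dosage compensation (8036474, rank 66).

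Searches over 93 gene families by name gave 2 past an adjusted p of 0.05, rps (14 of 30 genes with an IDR peak, Fisher's exact adjusted p = 2.4e-07) and rpl (11 of 38, adjusted p = 0.0016), both in the ribosomal list above. Over 2080 hexamers against the matched background, 78 were more and 82 less frequent (adjusted p at or under 0.05). GAGAGA (30.6% against 15% of summits) and AGAGAA came first, then GACGCA (16.8% against 6.63%, Fisher's exact adjusted p = 1.0e-07). The background was not matched on coding exons, which were rarer among IDR summits, and no test separated the hexamers from that difference.

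The larger share of IDR peaks on X was weighed against 3 explanations. Promoter content was to leave an odds ratio among promoter peaks whose interval includes 1, which it did (0.946 to 1.6). The odds ratio of 1.80 outside promoters, a test added after that value was seen, argues against promoter content as the whole cause. Among the other pooled peaks, X held 16% of those in promoter windows and 20.2% of those outside. IDR peaks lay in promoter windows more often (48.9% against 26.7%), which by these shares would lower their share on X. These values argue against promoter content as a part of the excess as well. Peaks with the octamer cannot be the whole cause either, since the odds ratio stayed at 1.36 without them (95% interval 1.15 to 1.61). Only peaks with an exact match within 100 bp of the summit were removed. Sites of the dosage compensation complex without such a match were not covered, so the complex itself is not excluded. Whether only some libraries carry the excess cannot be told apart from an excess in every library: the X share was larger in 4 of 4, the outcome written beforehand as speaking against this, but by the stricter rule set after these shares were seen the interval excluded 1 in replicates 1 and 3 alone. Apart from promoter content and the octamer, no biological explanation of the X share was tested, and X peaks at tRNA genes were not set apart.

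At egl-27 itself, extra copies of the region in the transgene may raise the signal. Such copies predicted more pooled peaks within 20 kb than around 95% of genes, and 99.995% of nuclear protein-coding genes had fewer than the 59 found there. The highest count around a gene more than 100 kb away was 43. The 5 kb bins from 6820008 to 6850007 held 7 to 9 pooled peaks each, while binding of EGL-27 to its own gene stays open, as no biological explanation was tested.

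Mitochondrial peaks led the IDR list although replicates 1 and 4 had none. Whether excess mitochondrial DNA in some libraries is behind this stays open: that 2 of 4 replicate lists had no mitochondrial peak is the observation that raised the question, so it tests nothing. Binding at discrete mitochondrial sites stays open as well: peaks covered 64.5% of that genome in replicate 2 and 52.2% in replicate 3, but 26.4% in the pooled list and 24.8% in the IDR list, and coverage follows the number and width of the peaks called. How reads of mitochondrial origin were treated is not given in the sources used here.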
